A study of Oedaleus asiaticus with 9 samples.

How the data were processed

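Small RNA libraries were made from total RNA of female *Oedaleus asiaticus* at the 3rd instar, 5th instar and adult stage, 3 libraries per stage. Per the labels' protocols, RNA of 15 to 30 nt was cut from a denaturing gel, ligated to adapters, reverse-transcribed, amplified and read as single ends of 50 bp on an Illumina HiSeq instrument. The aligner, the counting tool, the reference and their versions are not given in the sources used here. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

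The deposited table gives, per the file headers, raw read counts and TPM values of each miRNA entry in each library, with the entry's sequence. The counts are whole numbers and were not normalised by the authors. The authors' TPM values are each count scaled by a library total, not divided by length, with entries of 0 counts written as 0.01, as tested on the table. The library total implied by the TPM values exceeds the sum of the listed counts, which makes up 97.2% to 98.6% of it; the rest was not analysed here. A known entry bears a family name followed by x, y or z, whose meaning is not given in the sources used here, and these names are kept as written. Entries that the authors predicted bear only a running number and are referred to by length and sequence. Of the 365 entries, 23 share their whole sequence with another (9 sequences), and 5 of these sequences have identical counts in all their entries while 4 do not, so that reads of shared or nested sequences could be counted in more than 1 entry. No genome was used, so no positions are given.

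All tests used the counts. Library sizes were the sums of the listed counts (1462586 to 5309504, a 3.63-fold range), scaled by TMM factors of 0.854 to 1.166. Entries passing edgeR's expression filter by stage were tested, 179 in all, 28 of them predicted. A group-means model over all 9 libraries was fitted with edgeR 4.0.16 (robust quasi-likelihood fit) in R 4.3.3. An entry was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change above 1, the limits the study states; it names no test. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. The 3 comparisons were the 5th against the 3rd instar, the adult against the 5th instar and the adult against the 3rd instar, along with 1 test over all stages. Normalised CPM values are counts relative to the scaled library size, given as mean ± SD (n = 3 per stage).

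A total of 12 miRNA lists was fixed before the data were examined, by family number: the let-7 complex; juvenile hormone signalling and Kr-h1 targeting; ecdysone signalling and moulting; female reproduction; growth, insulin signalling and metabolism; the Hox cluster; apoptosis; early embryo families; and markers of muscle, of neurons, of plants and of vertebrates. Lists with at least 3 tested members (10 of the 12) were tested with fry from edgeR and limma 3.58.1, which asks whether members move on balance one way, adjusted over 30 tests; camera with an estimated correlation was the alternative. Also read, outside the planned count of lists, was the mixed p of fry, adjusted over the same 30 tests. It asks whether members change in either direction and does not compare a list with the other entries. Lists can share members, such as miR-8, miR-14 and bantam entries.

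Also fixed before the data were examined was the rule for named miRNAs. It takes, per comparison, called miRNAs whose 2 stages do not overlap and whose higher mean is at least 10 CPM (the 8 largest changes in each direction among known entries and 2 among predicted ones), the 5 most abundant called entries, and the 3 tested members of each list with the smallest p. It named 29, 27 and 31 entries in the 3 comparisons, and the 10 most abundant entries were named as well. Sequences are printed for some of the entries, and not for families of other organisms.

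The alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors, RLE factors, library totals without factors, totals without the 5 most abundant entries, no filter, a stricter filter (10 CPM in 3 libraries), only the 2 stages compared, the replicate number as a block, an adjusted p alone, entries of 1 sequence summed, known entries only, and leaving out each library in turn. Chosen after seeing the data were the totals implied by TPM, leaving out the most abundant entry, and leaving out entries of 18 or 19 nt. For the correlation between comparisons, so was the limit to entries with a count in every library.

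The procedure was tested on simulated counts with 40 changed entries in each of 20 simulations. For the 5th against the 3rd instar (median of 177 tested entries), 27.3% of 2-fold and 75.2% of 4-fold changes were recovered, with false calls making up 4.66% of calls. Here and below, simulations alike in their numbers of calls and of false calls entered the share of false calls once. For the adult against the 5th instar (176.5 tested) the shares were 28.2%, 76.5% and 2.31%, and for the adult against the 3rd instar (173 tested) 27.0%, 75.8% and 2.58%. A 2-fold change lies at the fold limit itself (median log2 estimates 1.01, 1.00 and 0.988), so the limit alone keeps many of them from being called. The 40 changed entries outnumber the 3, 2 and 7 called in the data, so the recovered shares need not hold there. No simulated change was called with the wrong sign. Figures were drawn with matplotlib 3.10.9.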

Results

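Small RNAs were sequenced from female *Oedaleus asiaticus*, a band-winged grasshopper of Asian steppe grassland, at 3 stages of development. The stages were the 3rd nymphal instar, the 5th nymphal instar and the adult, each sampled at an age of 3 days under normal feeding, with 3 libraries per stage and 9 in all. The samples' tissue or body part is not given in the sources used here. Nothing says whether the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The deposited table lists 365 miRNA entries, of which 291 carry a known family name and 74 were predicted by the authors. Total counts over these entries were 3042011, 3137710 and 5309504 in the 3rd instar libraries, 2010196, 1918962 and 2282357 in the 5th instar libraries, and 1462586, 3651172 and 3955332 in the adult libraries. Between 272 and 326 entries had at least 1 count in a library. An entry without a count could hold up to 0.565 CPM in the deepest library and 2.05 CPM in the shallowest, counting error only. Counts could not be attached to genome positions, because no reference genome was used here.

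A single predicted entry of 18 nt, GATGTCGATGGGGGCCGT, took most of the counts of every library. Whether this entry is a miRNA was not tested, as no reference genome was used. Its share was 70.6% ± 3.91 in the 3rd instar, 64.6% ± 3.09 in the 5th instar and 66.3% ± 6.98 in adults (SD, n = 3 each). The Wilson 95% interval of a single library's share was at most 0.159 percentage points wide. The most abundant known miRNA was miR-276-y (TAGGAACTTCATACCGTGCTCT), of a family that promotes synchronous egg hatching in locusts, with 11.99% ± 1.54, 14.7% ± 1.78 and 12.5% ± 1.67 of counts in the same order. It was followed by miR-8-y (3.78% ± 1.17 over the 9 libraries, SD) and miR-8-z (2.64% ± 0.813), of a family that controls body growth through insulin signalling in flies. Next came bantam-y (2.19% ± 0.521), which promotes growth and blocks cell death, and miR-31-x (1.49% ± 0.420). The muscle miRNA miR-1-y held 1.10% ± 0.281. Entries miR-305-x, miR-306-x and miR-14-y held 0.737% ± 0.176, 0.714% ± 0.119 and 0.671% ± 0.151. These 10 entries together held 93.6% ± 0.783 of the counts. No pair of libraries of 1 stage agreed within sampling noise, the lowest chi-square per degree of freedom being 69.1. The correlation of log values across entries, which are not independent replicates, was 0.929 to 0.981 within stages and 0.915 to 0.975 between stages.

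**Figure D1:**
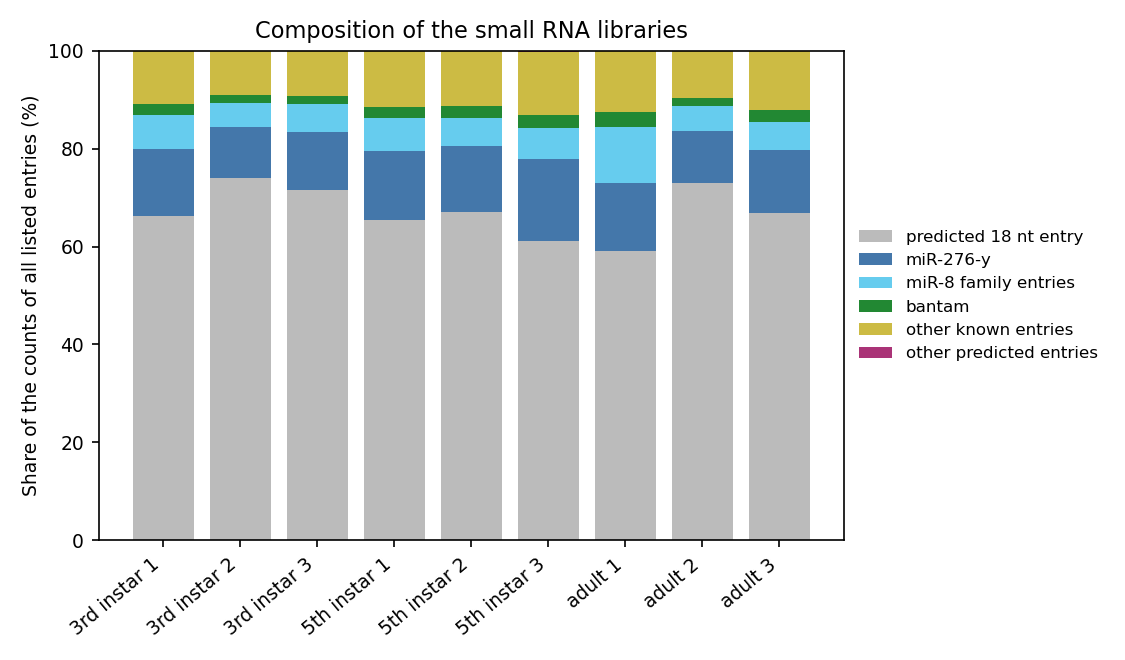
Share of the counts of all listed entries, in percent, taken by each class of entry in each of the 9 libraries (stacked bars, 1 per library). The grey part, the predicted 18 nt entry, ranged from 59.1% to 74.0%.

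The step from the 3rd to the 5th instar, 2 nymphal stages separated by moults, was compared to find miRNAs whose level differs between young and late nymphs. In the 5th instar, miR-2765-x (TGGTAACTCCACCACCGTTGGC) fell to 0.480 of its 3rd instar level, from 2671 ± 422 to 1283 ± 231 normalised CPM (SD, n = 3), a log2 fold change of -1.06 ± 0.16 (SE, adjusted p = 0.00233). A predicted entry of 23 nt, AGTTGGAAGTGGGGATCTCGGCA, rose from 50.9 ± 6.36 to 114.7 ± 13.005 CPM (log2 fold change 1.17 ± 0.17, adjusted p = 0.00233). Its sequence lies within that of miR-750-x, so reads could be counted in either entry. miR-750-x, chosen after its values were seen, was at 13.2 ± 4.46 CPM in the 3rd and 18.8 ± 7.51 in the 5th instar (log2 fold change 0.51 ± 0.43, adjusted p = 0.562), less than the gain of the shorter entry. The third called miRNA, miR-21-x, belongs to a family known from vertebrates and fell from 11.7 ± 5.44 to 1.11 ± 0.985 CPM (log2 fold change -3.31 ± 0.75, adjusted p = 0.0484). It had 0 counts in 1 of the 5th instar libraries, which allows up to 1.42 normalised CPM there (3 counts). A further miRNA, miR-14-y, acts in ecdysone signalling in flies and passed the adjusted p but not the fold limit, with 8855 ± 1269 CPM in the 3rd and 5662 ± 741 in the 5th instar (log2 fold change -0.65 ± 0.15, adjusted p = 0.0484).

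None of the 10 testable miRNA lists moved on balance one way between the nymphal stages (0 by fry, 3 at an unadjusted p under 0.05, 0 by camera). A mixed test, which asks whether members change in either direction, passed for 4 lists: ecdysone signalling (adjusted p = 0.000481), juvenile hormone signalling (0.00336), neuron markers (0.00932) and growth and insulin signalling (0.0220). The mixed test does not set a list against the other entries, so these passes do not show a change particular to the lists. Of the 14 tested members of the list on ecdysone signalling and moulting, 3 were higher and 11 lower in the 5th instar (adjusted p = 0.202), and miR-14-y alone passed when adjusted over the list alone, as it did in the list on growth and insulin signalling. miR-71-x, which together with miR-263 controls chitin metabolism at the moult in locusts, had a log2 fold change of -0.41 ± 0.15 (adjusted p = 0.195). In the let-7 complex, whose members rise with ecdysone at metamorphosis in flies, 6 of 8 entries were higher (adjusted p = 0.241), among them let-7-x at 0.36 ± 0.15 and miR-125-x at 0.32 ± 0.13 (adjusted p = 0.221 for both). Neuron markers were lower in 8 of 10 (adjusted p = 0.0571), and muscle markers were higher in 1 of 4 (adjusted p = 0.775). With library totals alone, miR-1-z and miR-133-z turned positive. In the Hox cluster list (adjusted p = 0.806), in which 4 of the 7 tested entries share 1 sequence, miR-993-y passed when adjusted over the list alone (log2 fold change -1.40 ± 0.38, adjusted p = 0.106 over all entries). The 4 tested entries of vertebrate families were all lower in the 5th instar (adjusted p = 0.0736), and 3 of them, miR-143-y, miR-29-y and miR-21-x, passed when adjusted over the list alone. miR-143-y, a smooth muscle miRNA of vertebrates, stood at 116 ± 75.2 CPM in the 3rd and 20.3 ± 9.40 in the 5th instar (log2 fold change -2.50 ± 0.70, adjusted p = 0.166). The remaining lists (juvenile hormone signalling, female reproduction, growth and insulin signalling, apoptosis) had adjusted p between 0.533 and 0.726. Median, mean and test differed in sign for the Hox, juvenile hormone, female reproduction and muscle lists.

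edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3 of 179 tested entries, 1 higher and 2 lower in the 5th instar, at an adjusted p under 0.05 and an absolute log2 fold change above 1. An unadjusted p under 0.05 was reached by 31, against 8.95 expected by chance, and DESeq2 called 10 (6 higher, 4 lower). The 2 stages did not overlap for 52 entries (29.1%, against 10% by chance). The count was 1 without 3rd instar 3, 5th instar 1 or 5th instar 3, 1 among known entries only and 1 (higher) when libraries were scaled by their totals alone, which shifted the median log2 fold change by 0.29. miR-21-x passed in 8 of 22 settings and miR-2765-x in 19 of 23, while the predicted 23 nt entry passed in all 22 in which it had a value.

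The step from the 5th instar to the adult, which crosses the final moult, was compared to find miRNAs whose level differs between late nymphs and adults. In adults miR-277-y (TAAATGCACTATCTGGTACGACA), which controls branched-chain amino acid breakdown in flies, rose 2.17-fold, from 1971 ± 240 to 4276 ± 1330 CPM (log2 fold change 1.12 ± 0.20, adjusted p = 0.0151). miR-2788-y (18 nt, CAATGCCCTTGGAAATCC) fell from 72.1 ± 15.4 to 26.2 ± 8.93 CPM (log2 fold change -1.45 ± 0.28, adjusted p = 0.0151). miR-9-z (TCTTTGGTTATCTAGCTGTATGA), of a family that shapes sense organ development in flies, passed the adjusted p but not the fold limit, at 5242 ± 289 CPM in the 5th instar and 3261 ± 170 in adults (log2 fold change -0.68 ± 0.13, adjusted p = 0.0151).

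No list moved on balance one way at this step (0 by fry, 1 at an unadjusted p under 0.05, 0 by camera), and the mixed test passed for 1, the neuron markers (adjusted p = 0.00699). All 4 tested muscle markers were higher in adults (adjusted p = 0.0938), and miR-1-y and miR-1-z passed when adjusted over the list alone but not over all entries. miR-1-y was at 9770 ± 517 CPM in the 5th instar and 13150 ± 2610 in adults (log2 fold change 0.43 ± 0.17, adjusted p = 0.296). Neuron markers were split, 5 higher and 5 lower (adjusted p = 0.586, with a test direction opposite in sign to the median and mean), miR-9-z being the member that passed. In the list on growth, insulin signalling and metabolism 11 of 17 were higher (adjusted p = 0.498), with miR-277-y as the member that passed. Of the ecdysone list 9 of 14 were higher (adjusted p = 0.498). miR-34-x, which ecdysone lowers in fly cells, had a log2 fold change of 0.67 ± 0.19 (adjusted p = 0.173). Hox cluster entries were lower in 6 of 7 (adjusted p = 0.304), with miR-10-x at -0.47 ± 0.17 (adjusted p = 0.296), though 4 of the 6 lower entries share 1 sequence. Vertebrate families were higher in 3 of 4 (adjusted p = 0.711), from levels such as 1.11 ± 0.985 CPM for miR-21-x in the 5th instar and 1.38 ± 0.760 in adults. The remaining lists had adjusted p between 0.245 and 0.775.

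edgeR called 2 of 179 entries, 1 higher and 1 lower in adults, 18 had an unadjusted p under 0.05 and DESeq2 called 2. The 2 stages did not overlap for 25 entries (14%, against 10% by chance). The count was 0 without 5th instar 1, 5th instar 2 or adult 3 and with only these 2 stages in the fit, and 1 without adult 1, without entries of 18 or 19 nt (miR-2788-y is 18 nt long) or with library totals alone (lower).

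The 3rd instar and the adult, the 2 ends of the series, gave the most calls, 7. miR-2765-x fell to 0.354 of its 3rd instar level, to 946 ± 24.8 CPM in adults (log2 fold change -1.50 ± 0.16, adjusted p = 0.000164). miR-277-y rose 2.49-fold from 1717 ± 112 CPM (log2 fold change 1.32 ± 0.20, adjusted p = 0.00123). The predicted 23 nt entry rose to 133.4 ± 5.62 CPM (log2 fold change 1.39 ± 0.17, adjusted p = 0.000397). miR-216-z (AAATATCAGTTGGTAATTCTGA) rose from 59.8 ± 8.02 to 121 ± 45.9 CPM (log2 fold change 1.01 ± 0.25, adjusted p = 0.0278). It contains the sequence of miR-283-x, which was chosen after its values were seen and had a log2 fold change of 0.66 ± 0.16 (adjusted p = 0.0262). miR-305-z rose from 2.60 ± 1.09 to 15.4 ± 12.4 CPM (log2 fold change 2.54 ± 0.65, adjusted p = 0.0282), with 29.5 CPM in adult 2 against 10.6 and 6.08 in the other adult libraries. It is a rare entry of its family. The abundant miR-305-x was at 6767 ± 958 CPM in the 3rd instar and 6810 ± 741 in adults (log2 fold change 0.0091 ± 0.16, adjusted p = 0.977). miR-305-y did not pass either (adjusted p = 0.283). miR-2788-y fell from 61.9 ± 9.63 to 26.2 ± 8.93 CPM (-1.23 ± 0.28 on the log2 scale, adjusted p = 0.0262) and miR-21-x fell to 1.38 ± 0.760 CPM (-2.97 ± 0.71, adjusted p = 0.0262). For each of the 7, the 3 adult libraries lay apart from the 3 libraries of the 3rd instar, as they did for 31.3% of all tested entries. The 7 were called on these same libraries, so their separation adds no support to the calls.

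**Figure D2:**
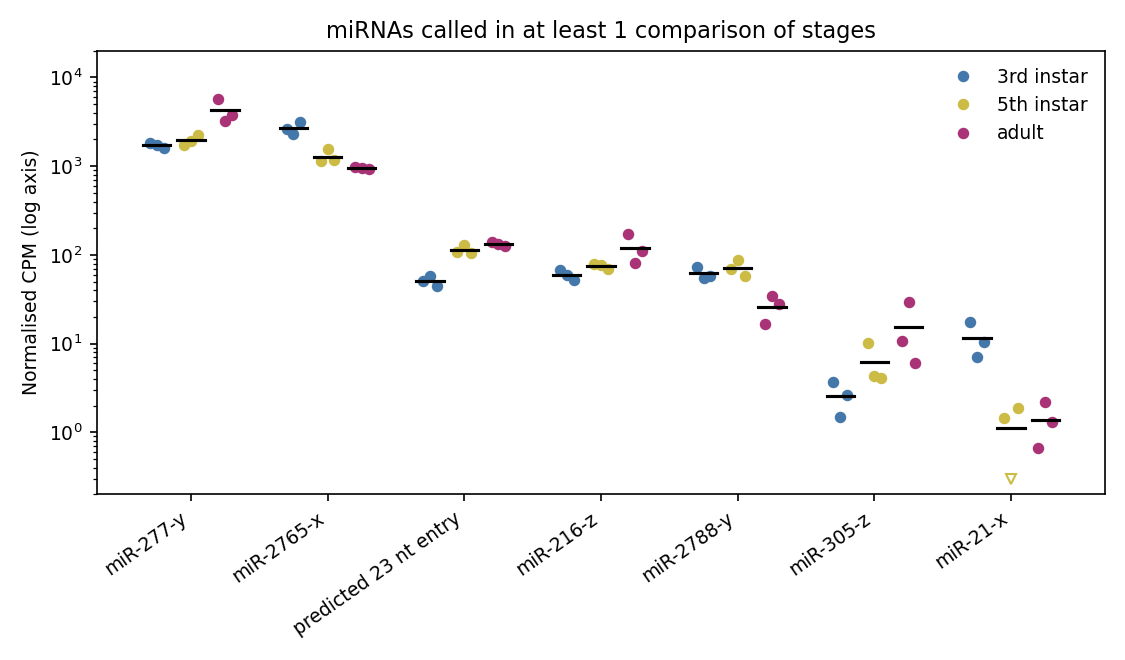
Normalised CPM (log axis) of the 7 miRNAs called in at least 1 comparison, with 1 point per library (n = 3 per stage) and black bars at the stage means; the open triangle marks a library with 0 counts, drawn near the bottom of the axis. miR-2765-x goes from 2671 to 946 CPM and miR-277-y from 1717 to 4276 CPM between the 3rd instar and the adult.

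Neuron markers were the only list to pass the test for a move on balance one way, in 1 of the 30 tests of a list in a comparison. Of their 10 tested members, 8 were lower in adults than in the 3rd instar, with a median log2 fold change of -0.29 (adjusted fry p = 0.0410; adjusted p = 0.652 with an estimated correlation). Among the settings that ended the call were RLE factors (adjusted p = 0.0553), library totals alone (0.584), totals without the 5 most abundant entries (0.0932), no filter (0.131), only these 2 stages in the fit (0.125), without the most abundant entry (0.0543) and without entries of 18 or 19 nt (0.0647). It ended as well without any of the 9 libraries except adult 2 (0.0240 without it, 0.0857 to 0.309 without each of the other 8). With known entries alone the adjusted p was 0.00652. Only miR-9-z passed by itself, at 6302 ± 626 CPM in the 3rd instar and 3261 ± 170 in adults (log2 fold change -0.95 ± 0.13, adjusted p = 0.000626). miR-137-y, a brain miRNA, was at -0.70 ± 0.32 (adjusted p = 0.142) and miR-124-y at -0.44 (adjusted p = 0.634). The miR-9 family also supplied miR-9-x (-0.30, adjusted p = 0.225) and miR-9-y (0.0052, adjusted p = 0.987), so members are not all separate families. The list was not tested without miR-9-z. Its pass therefore does not show a fall of neuronal miRNAs in general. All 4 muscle markers were higher in adults (adjusted p = 0.0736), and miR-1-x, miR-1-y and miR-1-z passed when adjusted over the list alone (log2 fold changes 0.86 ± 0.29, 0.42 ± 0.17 and 0.39 ± 0.15) and 0 over all entries. Of the ecdysone list, 6 members were higher and 8 lower (adjusted p = 0.486). Adjusted over the list alone 7 passed, with miR-14-y and miR-71-x lower (-0.62 ± 0.15 and -0.46 ± 0.15) and miR-8-x higher (0.68 ± 0.24). Over all entries 1 passed (miR-14-y, adjusted p = 0.0262). The more abundant miR-8-y and miR-8-z of the same list passed in neither way (0.29 and -0.063, adjusted p = 0.399 and 0.909 over all entries). The 7 that passed over the list alone include nested entries, miR-14-y within miR-14-z and miR-71-x within miR-71-z, so they are not 7 separate miRNAs. In the list on growth, insulin signalling and metabolism 11 of 17 were higher (adjusted p = 0.391), and 4 passed over the list alone and 3 over all entries, namely miR-277-y, miR-305-z and miR-14-y. The mixed test passed for 5 lists: neuron markers (adjusted p = 6.01e-06), growth and insulin signalling (0.000577), ecdysone signalling (0.00255), the let-7 complex (0.00699) and juvenile hormone signalling (0.00730). The mixed test does not set a list against the other entries, and 64 of the 179 tested entries had an unadjusted edgeR p under 0.05. Its passes therefore do not show a change particular to these lists. Camera, which asks whether a list moves one way relative to the other entries, passed for 0 lists in this comparison (adjusted p 0.652 to 0.901 for these 5). Hox cluster entries were lower in 7 of 7 (adjusted p = 0.241), though 4 of these 7 share 1 sequence. Among them was miR-10-y at -0.59 ± 0.26 (adjusted p = 0.128). Let-7 complex entries were higher in 6 of 8 (adjusted p = 0.404), juvenile hormone entries in 4 of 10 (adjusted p = 0.391), female reproduction entries in 10 of 17 (adjusted p = 0.605, with miR-305-z the member that passed) and apoptosis entries in 2 of 5 (adjusted p = 0.775). Vertebrate family entries were lower in 4 of 4 (adjusted p = 0.134), with miR-143-y at 19.5 ± 7.31 CPM in adults (log2 fold change -2.56 ± 0.70, adjusted p = 0.0710). It and miR-21-x passed when adjusted over the list alone. The lists of early embryo and plant families had 0 entries in the table.

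**Figure D3:**
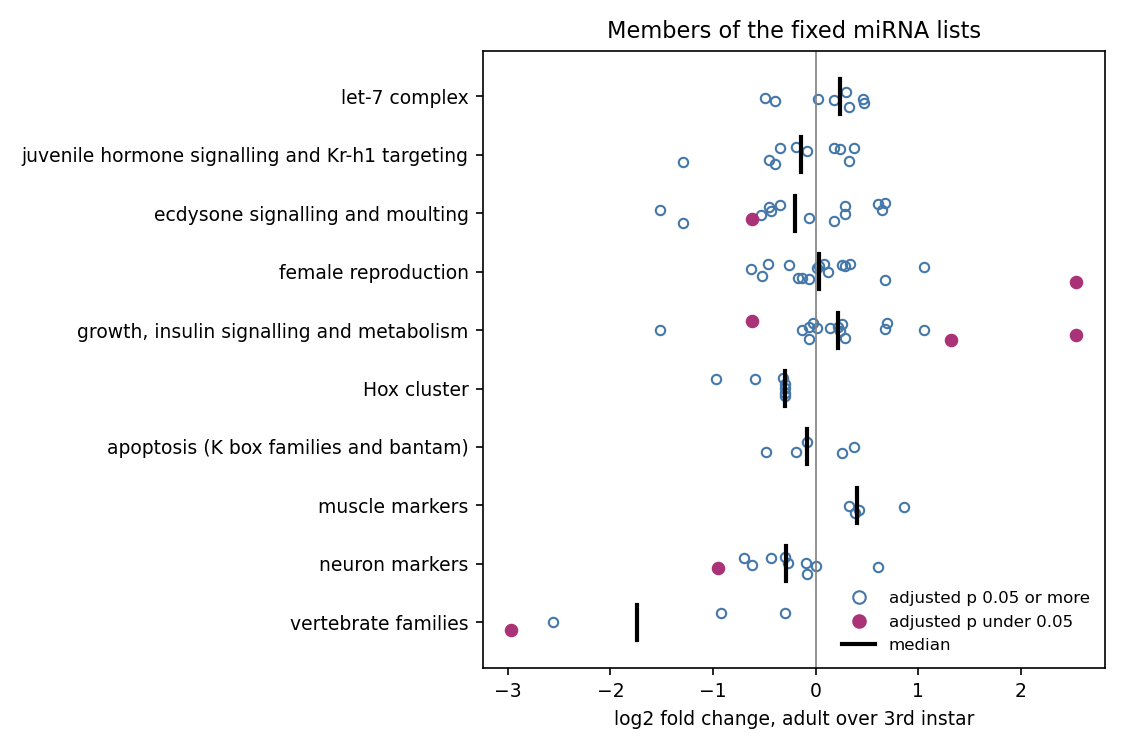
log2 fold change of each tested member of the 10 fixed lists, adult over 3rd instar (points; filled where the adjusted p over all entries is under 0.05), with the list median as a black bar. Neuron markers have a median of -0.29 and muscle markers of 0.40; the 4 entries of vertebrate families all lie below 0.

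edgeR called 7 of 179 entries between the 3rd instar and the adult, 4 higher and 3 lower, and DESeq2 called 15. An adjusted p under 0.05 without a fold limit was reached by 14 (7 higher, 7 lower), an unadjusted one by 64, and 56 entries did not overlap (31.3%, against 10% by chance). The count was 3 without 3rd instar 1 or without 3rd instar 3, and 19 (16 higher, 3 lower) with library totals alone, which shifted the median by 0.19. miR-2765-x and miR-277-y passed in all 23 settings, the predicted 23 nt entry in all 22 and miR-216-z in 9 of 23. miR-305-z lost its call without adult 2 or any 3rd instar library and with a filter of 10 CPM. miR-2788-y and miR-21-x passed in 18 of 22 settings each, and lost their calls without 3rd instar 1, 3rd instar 3, adult 1 or adult 3 (adjusted p up to 0.112 and 0.173).

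Across all 3 stages at once, 8 entries differed at an adjusted p under 0.05 and 44 at an unadjusted one. Of the 8, 5 were highest in the 3rd instar (miR-2765-x, miR-9-z, miR-14-y, miR-21-x and miR-279-z), 2 in the adult (miR-277-y and the predicted 23 nt entry) and 1 in the 5th instar (miR-2788-y). miR-279-z was chosen after its values were seen and belongs to a family that acts in olfactory neuron development in flies. It was at 8599 ± 785, 6354 ± 819 and 5293 ± 432 CPM in the 3rd instar, 5th instar and adult. The other tested entry of that name, miR-279-y, was at 1966 ± 73.4 CPM in the 3rd instar and 1651 ± 188 in adults. Its log2 fold change between them was -0.25 ± 0.12 (edgeR adjusted p = 0.175), so the fall of miR-279-z does not stand for the family. The count was 22 with DESeq2, 13 without entries of 18 or 19 nt, 4 without 3rd instar 1, 3rd instar 3 or adult 3, and 5 without 5th instar 1. No entry was called at both successive steps (0 by edgeR and 0 by DESeq2); at an unadjusted p under 0.05 there was 1, miR-2765-x, lower at each.

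All 3 entries called between the nymphal stages were also called between the 3rd instar and the adult in the same direction, while independent lists would share 0.0559. Both entries called between the 5th instar and the adult were called again in the same direction between the 3rd instar and the adult (0.0391 for independent lists). Simulated unchanged groups shared 0 calls in either case, but such groups give hardly any calls, so this value is no measure of what shared libraries add. Fold changes were therefore compared over the tested entries with a count in every library, leaving out 13 of 179, a restriction chosen after the values over all 179 were seen. Entries are not independent replicates. For the 2 comparisons with the 3rd instar, r was 0.668 against 0.489 in unchanged groups, and the covariance 0.386 against 0.111. For the 2 comparisons with the adult, r was 0.428 against 0.497 in unchanged groups, with a covariance of 0.204 against 0.113. Over all 179 tested entries r was 0.904 (0.508 in unchanged groups) and 0.296 (0.502), values that include fitted folds against stages at 0. The shared libraries were not split, since 1 part would have held a single library, and part of either overlap may come from them.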

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

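The totals implied by TPM, the analyses without the most abundant entry and those without entries of 18 or 19 nt were chosen after seeing the data. Over all alternatives, 1875 of the values of named miRNAs kept their direction and their side of the threshold, 55 no longer passed, 17 newly passed and 25 changed sign, none of which passed the threshold after changing sign. Of the 29, 27 and 31 named entries only 3, 2 and 7 were called, so most values that kept their side are of uncalled entries. All 55 losses fall on the called entries. These kept their call in anything from all settings with a value to 8 of 22 (miR-21-x between the nymphal stages). Replicate numbers were not taken to pair the samples. The deviations of same-numbered libraries correlated at -0.227 to 0.42, with 5 of 9 pairs above 0.1. Those of differently numbered libraries correlated at -0.434 to 0.283 (18 pairs). A pairing of some samples is not excluded by these values. With the number as a block, 2, 2 and 7 entries were called in the 5th against the 3rd instar, the adult against the 5th instar and the adult against the 3rd instar, 11 over all stages, and 0 lists in the adult against the 3rd instar. The block ended the call of miR-21-x between the nymphal stages. Between the 3rd instar and the adult it ended that of miR-216-z, and miR-10374-y was called instead.

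DESeq2 called 10 between the nymphal stages, 15 between the adult and the 3rd instar and 22 over all stages; the cause was not tested. Library totals without factors gave 1, 1 and 19 calls in the 3 comparisons and 0 lists for the adult against the 3rd instar, and shifted median log2 fold changes by 0.29, -0.10 and 0.19; other scalings shifted them by at most -0.05. An adjusted p alone gave 14 calls for the adult against the 3rd instar. Known entries alone gave 1 call and 1 list between the nymphal stages, the predicted 23 nt entry being left out there and miR-21-x losing its call (adjusted p = 0.0513). With 2 stages in the fit, which leaves fewer samples, the adult against the 5th instar had 0 calls. Without entries of 18 or 19 nt it had 1, and all stages 13.

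The neuron list, the 1 list called for the adult against the 3rd instar, went to 0 under RLE factors (adjusted p = 0.0553), totals without the 5 most abundant entries, no filter, the 2-stage fit, the block (0.152), camera (0.652), without the most abundant entry (0.0543) and without entries of 18 or 19 nt (0.0647). Its adjusted p ranged from 0.00652 to 0.652 over the alternatives. It passed with a filter of 10 CPM (0.0352) and entries of 1 sequence summed (0.0455), passed without adult 2 (0.0240) and failed without each of the other 8 libraries (0.0857 to 0.309).

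Leaving out 1 library gave 1 to 3 calls between the nymphal stages, 0 to 2 for the adult against the 5th instar, 3 to 9 for the adult against the 3rd instar and 4 to 9 over all stages. For lists it gave 0 to 1 between the nymphal stages (1 without adult 2) and 0 to 1 for the adult against the 3rd instar. DESeq2 gave no list tests and the 2-stage fit no value over all stages, and alternatives meant for tables without counts did not apply.

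Signs changed near 0. With library totals alone, log2 fold changes between the nymphal stages became 0.25 for miR-1-z, 0.29 for miR-133-z and 0.0125 for miR-9-z, and that of miR-2-y between the adult and the 3rd instar became 0.00341. miR-133-z turned to 0.0184 in the 2-stage fit, 0.00679 with sequences summed, 0.0280 without the most abundant entry and 0.0158 without 18 or 19 nt entries. Leaving out 1 library gave ranges between the nymphal stages of -0.0787 to 0.0341 for miR-1-z, -0.0402 to 0.142 for miR-133-z, -0.00629 to 0.157 for miR-13-y and -0.126 to 0.440 for iab-4-x. For the adult against the 5th instar the ranges were -0.216 to 0.972 for miR-21-x and -0.375 to 0.981 for miR-30-x.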

Other observations

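The splits of the libraries were planned before their results were seen, and the other tests below were chosen after the patterns they concern had been noticed. Short entries make up much of the table. Of the 365 entries, 88 are 18 nt long, and 15 of the 81 known ones of that length (18.5%) end in CCA, as mature tRNAs do, against 0 of 169 known entries of 21 nt or more and 1.56% for any 3 given bases (Fisher's exact test, two-sided, p = 1.75e-08; entries are not independent). These 15 entries summed to 253 ± 77.5 normalised CPM in the 3rd instar, 330 ± 64.9 in the 5th instar and 456 ± 185 in adults (SD, n = 3). All 9 tested ones were higher in adults than in the 3rd instar, with a median log2 fold change of 0.77. As a set they did not pass edgeR's fry test (unadjusted p = 0.117). A few entries peaked in a single library. miR-8503-z had 1493 counts in 5th instar 3 and 8 to 32 in the other libraries, and miR-8516-z had 314 there and 2 to 9 elsewhere.

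Of the 4 tested entries of vertebrate miRNA families, miR-21-x passed over all entries as higher in the 3rd instar, and the list did not pass (adjusted p = 0.0736 and 0.134 against the 5th instar and the adult). miR-143-y, which did not pass either (0.166 and 0.0710), had 168.4, 29.5 and 149 normalised CPM there against 9.50 to 28.0 in the 6 later libraries. RNA from a vertebrate in the 3rd instar libraries is a candidate explanation, and it would also raise the 10 members of the list that were too rare to be tested. Summed, these were 2.48 times as high on average in the 3rd instar as in the later libraries (8.35, 4.10 and 15.0 CPM against 1.98 to 5.64; two-sided exact permutation test over 84 choices of 3 libraries, p = 0.0357). Such RNA remains possible, but the sum was tested on the libraries in which it was noticed, 3rd instar 2 lies below 2 of the later libraries, and miR-24-x had 0 counts in all 3 libraries of the 3rd instar but not in all later ones. Among the 10 rare members, miR-103-y and miR-107-z had identical counts in every library. The same reads may therefore have entered the sum more than once, and the test was not repeated without that. The labels name 0 preparation batches, so a preparation batch shared by the 3rd instar libraries cannot be told apart from the stage.

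A total of 13 entries had 0 counts in all 3 libraries of the 3rd instar and at least 20 in the other 6 together, against 2 such entries for the 5th instar and 1 for the adult. They summed to 73.1, 13 and 64.8 CPM in the 5th instar libraries and 28.7, 97.8 and 50.3 in the adult ones. Lower depth is argued against by the mean total of the 3rd instar libraries, 1.5 times that of the later ones. A chance choice of libraries remains undecided. With at least 20 counts elsewhere, 1 of 84 choices of 3 libraries left as many entries at 0 (the real one; highest other 10), but the stage and this limit were chosen after the counts were seen. Allowing for any of the 3 stages, the share of 280 divisions of the libraries with as many was 0.0357 at limits of 20, 30 and 50 counts, but 0.0714, 0.107 and 0.0679 at 1, 5 and 10. Of the 13, 12 are 18 or 19 nt long. The 96 other known entries of that length reached 0.724 of their later mean in the 3rd instar (lowest library 0.558). This argues against a size window that left nearly all short reads out. It cannot exclude a partial loss, as these entries summed to 1150 ± 333 normalised CPM in the 3rd instar, 1660 ± 312 in the 5th instar and 1530 ± 413 in adults. Chance, a partial loss of short reads, stage, and a batch that coincides with stage, stay open as possible explanations.

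The ratio of a longer entry to a shorter one nested in it was higher on average in the 3rd instar, without passing a test between 2 stages. Over 24 tested pairs, the log2 ratio, centred per pair with 0.5 CPM added to each, averaged 0.21 ± 0.19 in the 3rd instar, -0.10 ± 0.04 in the 5th instar and -0.10 ± 0.16 in adults (SD, n = 3). The change from the 3rd instar to the 6 later libraries was -0.31 (two-sided exact permutation p = 0.0238 over 84 choices), a grouping chosen after the adult alone against the 3rd instar had given p = 0.2 (exact). The 5th instar alone against the 3rd gave p = 0.1 (exact, the smallest possible). 3rd instar 2 (0.0229) lies below adult 1 (0.0767), and from the 5th instar to the adult 12 of the 24 pairs were lower (mean change 0.00368). The change from the 3rd instar to the later libraries kept its direction without each library in turn. It was -0.21 without 3rd instar 1, the library with the highest ratio (0.399), and farther from 0 without each of the other 8. The permutation test was not repeated on these reduced sets, so whether its p depends on 3rd instar 1 was not tested. A length trend over all entries may contribute and remains undecided: among 72 known entries of 21 nt or more outside the pairs the slope per nt was 0.019 (95% interval -0.177 to 0.215, against -0.153 for the pairs), a length limit set after 106 entries of all lengths had given -0.383 (-0.563 to -0.203). Some pairs join entries of different families, such as miR-81-z within bantam-y. Stage itself stays open, and no biological explanation was tested.

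For the calls over all 3 stages, 1 of 100 drawn splits of the 9 libraries into groups of 3 (the real one) gave as many as 8. The highest other gave 5. This argues against a chance assignment of these libraries to the stages. Chance differences between animals cannot be excluded by it, because nothing says whether the replicates came from separate animals. For pairs of stages the 10 splits of 6 libraries are too few for a share under 0.05. The real counts were 3 between the nymphal stages (highest other 2), 2 between the 5th instar and the adult (highest other 0) and 7 between the 3rd instar and the adult (highest other 0). For lists they were 0 between the nymphal stages and 0 between the 5th instar and the adult, which all 10 splits reach, and 1 between the 3rd instar and the adult, which 2 of 10 splits reach (highest other 1).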
